A study of Homo sapiens with 12 samples.

How the data were processed

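DDX1 is an RNA helicase. RNA immunoprecipitation followed by sequencing (RIP-seq) recovers RNA with an antibody against a protein of interest and sets it beside the RNA of the same lysate (Input). The samples were IMR90 cells, an established line of human embryonic lung fibroblasts, in 3 conditions. The labels call them Pro (control vector), OIS (ectopic Ras, used for senescence induction) and OIS-LMB (ectopic Ras with LMB, which the labels do not spell out). Each condition had 2 Input and 2 DDX1 RIP libraries, titled biological replicates, so that 12 libraries formed 6 groups of 2. Per the labels' protocols, cells were kept at low oxygen, RNA was recovered with a Magna RIP kit, and stranded libraries were made from total RNA with ribosomal RNA depletion. The protocol also names an isotype IgG. IgG libraries and R-loop data were not analysed here, so no enrichment below is corrected for RNA that binds unspecifically.

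The deposited tables hold raw counts, made by the authors, one table per condition with its 4 libraries. Per the file headers, rows are genes or transposable elements. There were 60110 rows in every table, of which 58780 carry an Ensembl gene ID and 1330 the name, family and class of a repeat subfamily. A subfamily's count covers its copies across the genome, so the count does not tell which copies or host transcripts it came from. Per the submitters' processing notes, FastQC 0.11.9, Trim Galore 0.6.5, cutadapt 1.18, STAR 2.7.10b and the genome build GRCh38 were used. The counting program, its handling of strand and of reads with several matches, and the annotation release are not given in the sources used here. Gene rows therefore cannot be told apart from overlapping or antisense genes where these share reads.

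The tables pair no gene ID with a symbol, and the reference table of gene names used here matched none of the IDs. Genes are therefore given as counts, with 2 IDs that were higher and 2 that were lower in RIP. Gene lists, a label check on the Ras and senescence genes, and a scaling without mitochondrial, ribosomal and small structured RNA genes had been fixed before the data were examined. None of the 3 could be applied without symbols. Tests, alternatives and the rule for named features were also fixed before the data were examined. This plan gave the differences between enrichments an unpaired fit without a replicate block, so the paired fit of these differences was not part of it. The repeat families as sets, against all features or the other repeats, the shares of counts in repeat classes, the comparison of OIS-LMB with Pro enrichment, the adjustment over repeats alone and the alternatives within the paired fit were chosen after the row names or values had been seen.

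Totals ran from 40100122 to 61995813 counts per library, so that counting error is small beside the spread between replicates for all but rare features. Pseudoautosomal genes are listed once for X and once for Y. Of these 45 pairs of rows 40 had identical counts in all libraries, and all 90 rows were left out, at most 0.0431% of a library's counts. Among 18679 rows with at least 100 counts, 36 had the same counts in every library as another row. Replicates of every group differed by far more than counting noise. Their chi-square per degree of freedom lay between 185 and 386. No library was counted as a repeat of another.

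Counts were analysed in R 4.3.3 with edgeR 4.0.16. Rows passing filterByExpr (minimum count 10, minimum total 15) were kept, which left 19410 genes and 978 repeat subfamilies, 20388 features in all. Libraries were scaled by TMM factors. A negative binomial model with 6 group means and robust quasi-likelihood dispersions was fitted to all 12 libraries, with 6 residual degrees of freedom. Contrasts were tested with the two-sided quasi-likelihood F test, and p-values were adjusted by Benjamini-Hochberg over all features of a contrast at a threshold of 0.05. Fold changes are given on the log2 scale, with a standard error derived from the F statistic. Levels are given as CPM, counts divided by the library total and scaled to a common total, with TMM factors where a subfamily is named. The difference of 2 enrichments was tested as an interaction contrast.

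Input and RIP of the same condition and replicate number deviated together. The correlations of their replicate differences across features were 0.476 in Pro, 0.681 in OIS and 0.747 in OIS-LMB, all above 0.1. The numbers were therefore taken to pair Input and RIP within a condition, from the data and not from a statement in the labels. Values from the fit with this replicate block within condition, which has 3 residual degrees of freedom, stand beside results they change and are called paired. Libraries of the same number in OIS and OIS-LMB also deviated together, with correlations of 0.609 between their Inputs, 0.671 between their RIP libraries, and 0.563 and 0.591 between Input and RIP, whereas the correlations of Pro with OIS or OIS-LMB libraries ran from 0.0587 to 0.19 and were not all above 0.1. They were 0.0696 for OIS Input and 0.185 for OIS-LMB Input with Pro Input, and 0.19 and 0.189 for their RIP libraries with Pro RIP. Pairing with Pro was therefore not excluded, and the paired fit does not assume it. Because OIS and OIS-LMB deviated together, the fit with the replicate number as a block over all libraries stands beside the comparison of OIS-LMB with OIS Input. That fit assumes the same replicate effect in all libraries, those of Pro included, which the correlations with Pro do not establish.

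Named features are repeat subfamilies with an adjusted p below 0.05, a mean log2 CPM of at least 1 and no overlap between the libraries compared. The last condition was not applied to differences between enrichments. The 10 with the largest positive and the 10 with the largest negative log2 fold change qualify. The rule was written for gene symbols and was applied to the features that carry a name. Families with at least 10 tested members (11 of them), all repeats and all satellites were tested as 13 sets with camera of limma 3.58.1, at a preset correlation of 0.01 and with an estimated one. The families were also tested against the other repeats alone. Class shares were tested by an exact permutation of Input and RIP labels within conditions, two-sided, over 216 arrangements, so that the smallest p is 0.00926. The 10 such tests were adjusted together. For numbers of genes with a count, libraries were thinned to 40082800 counts.

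Alternatives were relative log expression factors, library-size scaling alone, DESeq2 1.42.0, no low-count filter, a filter of 5 CPM in 2 libraries, fits on the groups compared, replicate blocks, a minimum log2 fold change of 1, adjustment over repeats alone, and leaving out each library.

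The steps were tested on simulated data with 200 of the 20388 features changed. A first test, with 100 features changed 2-fold and 100 changed 4-fold, recovered 1% and 39% of them for RIP against Input in Pro and 0% of both for the OIS minus Pro difference. The paired fit recovered 0% and 19% in Pro and 0% of both for the difference, where all 3 of its calls were false. A second test was then drawn with 50 features at each of 4 sizes, the larger sizes being added because the first had recovered few features. The fits were not changed between the tests. For RIP against Input in Pro, 0% of the 2-fold, 66% of the 4-fold, 86% of the 8-fold and 96% of the 16-fold changes were recovered, with 5 false calls among 129. The paired fit recovered 0%, 52%, 86% and 96%, with 9 false calls among 126. For the OIS minus Pro difference, the recovery was 0%, 18%, 50% and 84% at these sizes, with 2 false calls among 78, and the paired fit recovered 0%, 8%, 46% and 82%, with 4 false calls among 72. For OIS against Pro Input it was 0%, 36%, 84% and 90%, with 5 false calls among 110. Only 200 features were changed, whereas on the data edgeR called 8290 features in Pro RIP and 3041 between OIS and Pro Input. An adjusted p under 0.05 was therefore harder to reach in the simulation. Of the 8290 calls in Pro RIP, 7375 had a log2 fold change of at least 1, so changes under 2-fold were also called. The recovery does not carry over to these 2 comparisons. In both tests the libraries were simulated without any deviation shared by Input and RIP of the same number. The figures for the paired fit therefore do not describe how it performs on these data, where such deviations were seen. With no set changed, camera called 0 of the 13 sets in each of these 3 comparisons, and it called the L1 set in each when that set alone was raised. Simulated features were drawn independently, whereas members of a set moved together in the data, with an estimated correlation of 0.739 for L1 in Pro. The set result therefore does not cover sets with correlated members. Since simulated OIS minus Pro differences of 4-fold or less were mostly missed, a count of 0 called differences does not show that enrichments were alike.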

Results

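The series asks which RNAs are recovered with the helicase DDX1 in proliferating and in senescent IMR90 fibroblasts. DDX1 RIP and Input RNA were sequenced from vector control cells (Pro), cells with ectopic Ras (OIS) and cells with ectopic Ras and LMB (OIS-LMB), with 2 libraries in each of the 6 groups. Totals ran from 40100122 counts in Pro Input replicate 1 to 61995813 counts in OIS RIP replicate 2, and Input libraries reached at most 49923180 counts. Repeat subfamilies took 1.27% to 2.73% of a library's counts and genes the rest. All errors of fold changes are standard errors, and every group has n = 2.

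Counts from transposable elements were higher in DDX1 RIP than in Input. LINE elements, which include the autonomous retrotransposon L1, averaged 6744 CPM in RIP and 4468 CPM in Input. SINE elements, mostly Alu, averaged 7343 and 5304 CPM, LTR elements of endogenous retroviruses 3163 and 2388 CPM, and DNA transposons 1745 and 1259 CPM. SVA retroposons, composite elements of hominids, averaged 116 CPM in RIP and 63.5 CPM in Input. Each of these 5 classes was higher in 6 of 6 RIP libraries than in the Input of the same condition and number, with adjusted p of 0.0265 to 0.0309 in the exact permutation test over 10 measures. Satellites were higher in 5 of 6 RIP libraries than in that Input, and above both Inputs of their condition in 4 of 6 (adjusted p = 0.0309). The single row of the RNA class, the small nuclear RNA 7SK, which holds the elongation factor P-TEFb inactive, went the other way. It averaged 48.2 CPM in RIP and 1226 CPM in Input and was lower in 6 of 6 libraries (adjusted p = 0.0265, from the smallest p the exact test can give).

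Repeats together made up 1.92% of RIP and 1.48% of Input counts, a difference of 0.447 percentage points (exact permutation p = 0.037, adjusted p = 0.037), and their share was higher in 6 of 6 RIP libraries than in the Input of the same condition and number. Without OIS-LMB RIP replicate 1, the library with the most repeat counts, the difference was 0.266 points (exact permutation p = 0.157). The exact p, which does not use the pairing, stayed under 0.05 only when the library left out was OIS Input replicate 1, OIS RIP replicate 2 or OIS-LMB RIP replicate 2. At equal depth, 23421 gene rows had a count in RIP and 24299 in Input (exact permutation p = 0.0185, adjusted p = 0.0265).

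**Figure D1:**
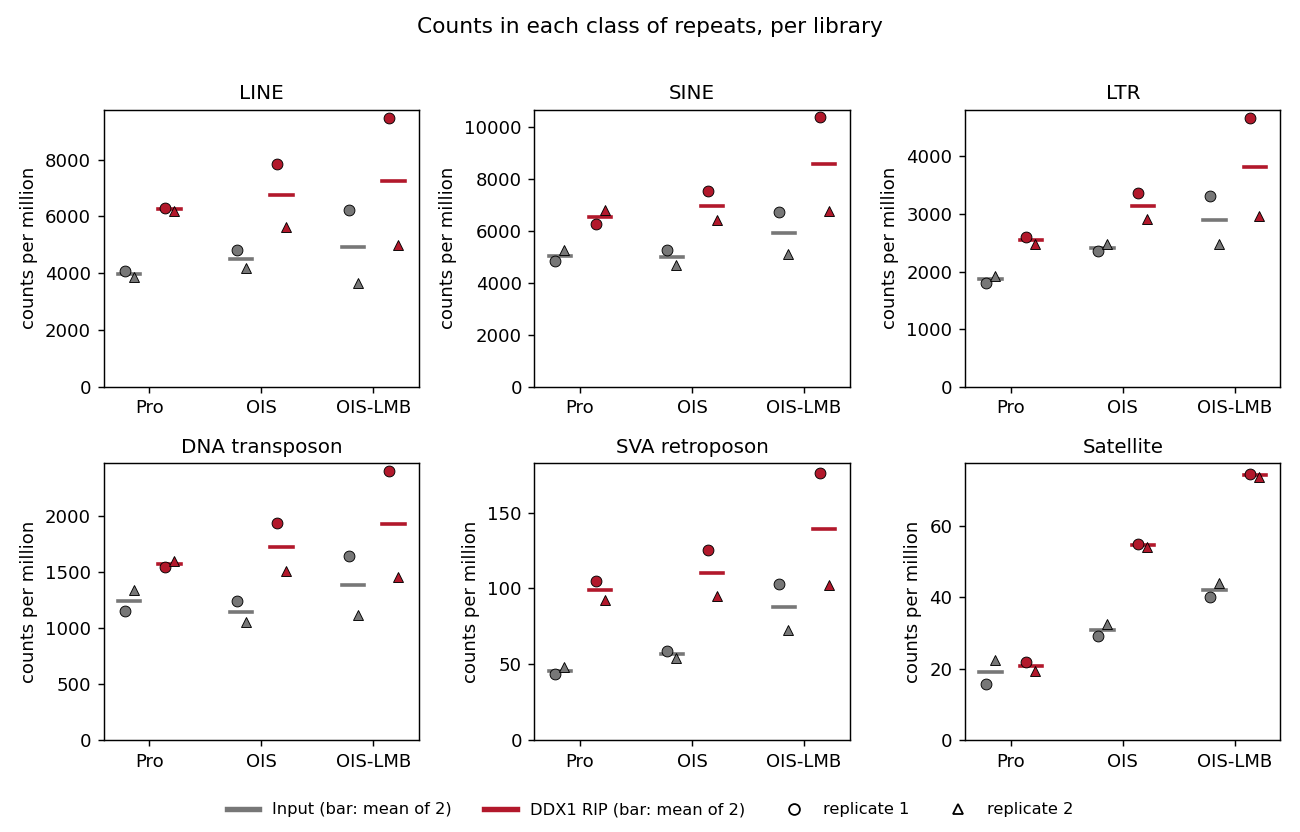
CPM in 6 classes of repeats (y axes, starting at 0) for Pro, OIS and OIS-LMB, with Input in grey, DDX1 RIP in red, circles for replicate 1, triangles for replicate 2 and bars for the mean of 2 libraries. SINE counts were higher in 6 of 6 RIP libraries than in both Inputs of their condition, while satellite counts in Pro RIP (mean 20.6 CPM) lay close to those in Pro Input (mean 19.0 CPM).

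In Pro cells, gamma satellite GSATII, a pericentromeric repeat, was 6.89-fold higher in RIP than in Input (log2 2.78 ± 0.42, edgeR adjusted p = 0.000676), at 1.85 ± 0.44 against 0.266 ± 0.012 CPM (SD, n = 2). The Input level of GSATII rests on few counts, so its small SD there says little about its precision. The satellite LSAU was higher by log2 2.61 ± 0.44, the CR1 element CR1-L3A_Croc was 6.52-fold higher, and the L1 elements L1M6B and HAL1ME were higher by log2 2.51 ± 0.35 and 2.13 ± 0.30. Also among the 10 named increases were the ERV1 elements LTR103_Mam (2.41), LTR64 (2.13) and HUERS-P3b-int (1.90) and the DNA transposons MER99 (2.19) and MER126 (2.10). Lower in RIP were MER11B, an LTR of the ERVK family, by log2 -4.79 ± 0.48, 7SK by -3.72 ± 1.06, LTR48B by -3.40 ± 0.37, LTR70 by -1.02 ± 0.32 and the centromeric alpha satellite ALR/Alpha by -0.67 ± 0.23 (adjusted p = 0.0386).

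By family in Pro, 41 of 129 tested L1 subfamilies were higher in RIP and 0 lower (camera adjusted p = 2.18e-06). The same held for 25 and 0 of 75 ERVL-MaLR, 21 and 0 of 113 ERVL and 9 and 0 of 50 Alu subfamilies, with camera adjusted p of 0.000258, 0.00457 and 0.00534. Of 263 ERV1 subfamilies 32 were higher and 3 lower (adjusted p = 0.00946). With an estimated correlation each of these sets had an adjusted p = 0.699. Against the other repeats alone, L1 (camera adjusted p = 2.82e-05) and ERVL-MaLR (0.0382) stood higher and ERV1 lower (0.0346), each with an adjusted p = 0.972 at an estimated correlation. ERVL (adjusted p = 0.913) and Alu (0.344) did not pass against the other repeats. Of 15 satellites 2 were higher and 2 lower (adjusted p = 0.272). The paired fit called 103 L1 subfamilies higher and 1 lower, 49 and 2 ERVL-MaLR, 49 and 1 ERVL and 31 and 0 Alu. For ERV1 its counts were 94 and 10, and for satellites 4 and 3.

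In all, edgeR called 3636 genes and 175 repeat subfamilies higher and 4472 genes and 7 subfamilies lower in Pro RIP, 8290 features together. The paired fit called 12855 features, with 464 subfamilies higher and 23 lower. The median log2 enrichment was 0.60 over repeats and -0.02 over genes. Library-size scaling alone lowered the median of all features by 0.11 in Pro, 0.29 in OIS and 0.30 in OIS-LMB, and left repeats above genes by 0.60, 0.76 and 0.69. Adjusted over repeats alone, 70 subfamilies were higher and 2 lower, and library-size scaling called 110. The 182 called subfamilies became 79 without Pro Input replicate 1, 88 without Pro Input replicate 2, 98 without Pro RIP replicate 1 and 57 without Pro RIP replicate 2, where the total was 5391. The call of 7SK was lost without Pro Input replicate 1 (log2 -3.60) or Pro RIP replicate 2 (-2.93), that of LTR64 without Pro Input replicate 1 (1.90) or Pro RIP replicate 2 (1.07), and that of ALR/Alpha without 8 of the 12 libraries, among them Pro RIP replicate 2 (-0.51) and Pro Input replicate 2 (-0.49). ALR/Alpha was also not called under relative log expression factors (adjusted p = 0.0545), without a low-count filter (adjusted p = 0.251) or in a fit on the Pro libraries alone (adjusted p = 0.119), nor LTR70 in the last 2 of these (adjusted p = 0.123 and 0.0508). LTR70 was not called without Pro Input replicate 2 (-0.69) or either Pro RIP replicate (-1.05 and -1.06), nor LTR103_Mam without Pro Input replicate 1 (adjusted p = 0.053), Pro Input replicate 2 (log2 2.18) or Pro RIP replicate 1 (2.26).

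In OIS cells, the ERV1 element LTR64 was 6.36-fold higher in RIP (log2 2.67 ± 0.49, edgeR adjusted p = 0.00187). LTR1A2 was higher by 2.44 ± 0.48, GSATII by 2.34 ± 0.39, the ERVL element LTR84a by 2.25 ± 0.36, the DNA transposons Charlie17 and MER46C by 2.20 ± 0.25 and 2.07 ± 0.26, and L1M6B by 2.17 ± 0.35. CR1-L3A_Croc (2.15), MER51C (2.02) and LTR103_Mam (2.01) completed the 10. 7SK was lower by log2 -4.65 ± 1.11, MER11B by -3.63 ± 0.46 and LTR48B by -3.15 ± 0.37. LTR7 and HERVH-int, the LTR and the internal part of the endogenous retrovirus HERV-H, were lower by -2.28 ± 0.41 and -2.33 ± 0.61.

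MER31B (-1.89), MER34B-int (-1.49) and LTR26 (-1.07), all ERV1, were the other named decreases in OIS. The paired fit no longer called HERVH-int (log2 -2.05 ± 0.70, adjusted p = 0.0701). Of 129 L1 subfamilies 30 were higher in OIS RIP, of 75 ERVL-MaLR 31, of 74 hAT-Charlie 19 and of 50 Alu 13, with 0 lower in each family. Their camera adjusted p were 0.000123, 0.000123, 0.000402 and 0.00124. ERV1 had 39 higher and 7 lower of 263 (adjusted p = 0.0104). With an estimated correlation the adjusted p was 0.598 for each of these sets. Against the other repeats alone, only ERV1 passed, and it stood lower (camera adjusted p = 0.000276, 0.932 with an estimated correlation). The paired fit called 88 L1, 54 ERVL-MaLR, 45 hAT-Charlie and 36 Alu subfamilies higher and 0 lower in each family. For ERV1 it called 89 higher and 13 lower.

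The OIS fit called 3742 genes and 225 subfamilies higher and 4568 genes and 10 subfamilies lower, 8545 features, and the paired fit 13150, with 512 subfamilies higher and 23 lower. Higher features were 46.4% of the calls, and 34.6% with library-size scaling alone, which called 114 subfamilies. Adjusted over repeats alone, 127 subfamilies were higher and 8 lower. The 235 called subfamilies became 138 without OIS Input replicate 1, 81 without OIS Input replicate 2, 103 without OIS RIP replicate 1 and 145 without OIS RIP replicate 2. HERVH-int was not called without OIS Input replicate 2 (log2 -1.08), OIS RIP replicate 1 (-2.23) or OIS RIP replicate 2 (-2.44), nor LTR103_Mam without OIS RIP replicate 2 (0.86), OIS Input replicate 1 (adjusted p = 0.171) or Pro RIP replicate 1 (1.97). MER34B-int lost its call without OIS RIP replicate 2 (adjusted p = 0.196) or either OIS Input replicate (log2 -1.45 and -1.52), and LTR26 without OIS Input replicate 1 (-0.93) or either OIS RIP replicate (-1.10 and -1.03). A fit on the OIS libraries alone did not call HERVH-int (adjusted p = 0.0612) or LTR103_Mam (adjusted p = 0.109), which library-size scaling alone did not call either (adjusted p = 0.0638), and LTR26 was not called without a low-count filter (adjusted p = 0.0775).

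In OIS-LMB cells, LTR64 was 6.13-fold higher in RIP (log2 2.62 ± 0.49, edgeR adjusted p = 0.00242). L1M6B was higher by 2.35 ± 0.35, LTR84a by 2.31 ± 0.36, CR1-L3A_Croc by 2.27 ± 0.47, the DNA transposon MER45R by 2.06 ± 0.30, Charlie17 by 1.92 ± 0.24 and MER46C by 1.89 ± 0.26. The others of the 10 were MLT1A1-int (1.96), LTR103_Mam (1.96) and HUERS-P3b-int (1.95). 7SK was lower by log2 -4.76 ± 1.12, MER11B by -3.43 ± 0.45, LTR48B by -2.20 ± 0.35, LTR7 by -1.56 ± 0.40, MER31B by -1.32 ± 0.40 and LTR26 by -1.08 ± 0.28.

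By family in OIS-LMB, 29 of 129 L1, 22 of 75 ERVL-MaLR, 19 of 50 Alu and 16 of 74 hAT-Charlie subfamilies were higher in RIP and 0 lower (camera adjusted p = 2.53e-05, 0.000102, 0.000324 and 0.000472). Each of these 4 sets had an adjusted p = 0.631 with an estimated correlation. Against the other repeats alone, L1, ERVL-MaLR and Alu stood higher (camera adjusted p = 0.0354 each) and ERV1 lower (7.3e-05), each with an adjusted p = 0.993 at an estimated correlation, while hAT-Charlie did not pass (0.33). The fit called 3494 genes and 190 subfamilies higher and 4103 genes and 9 subfamilies lower, 7796 features, and the paired fit 12793, with 483 subfamilies higher and 23 lower. Higher features were 47.3% of the calls, and 33.0% with library-size scaling alone, which called 89 subfamilies. Adjusted over repeats alone, 91 subfamilies were higher and 5 lower. By family, the paired fit called 97 L1 subfamilies higher and 1 lower. It called 47 ERVL-MaLR, 35 Alu and 45 hAT-Charlie subfamilies higher and 0 lower. The 199 called subfamilies became 54 without OIS-LMB Input replicate 2, 75 without OIS-LMB RIP replicate 1 and 130 without Pro RIP replicate 1. A fit on the 4 OIS-LMB libraries alone called 4519 features, 39 of them subfamilies, and ended the calls of HUERS-P3b-int, CR1-L3A_Croc, MLT1A1-int, MER31B, LTR103_Mam, LTR7 and LTR26 (adjusted p of 0.05 to 0.082). LTR103_Mam was also not called with library-size scaling alone (adjusted p = 0.072), nor LTR26 without a low-count filter (adjusted p = 0.0728). Without OIS-LMB RIP replicate 2 the calls of 7SK (log2 -4.22), LTR7 (-1.08), MER31B (adjusted p = 0.15), LTR26 (log2 -0.91) and LTR103_Mam (1.60) were lost, and without OIS-LMB RIP replicate 1 that of MLT1A1-int (1.44). Without OIS-LMB Input replicate 2 those of MLT1A1-int (1.55), LTR7 (-1.33) and MER31B (-1.40) were lost, and without OIS-LMB Input replicate 1 those of MER31B (-1.24), LTR26 (-0.94) and LTR103_Mam (1.47). LTR103_Mam also lost its call without each of the 4 Pro libraries (log2 1.89 to 1.96).

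**Figure D2:**
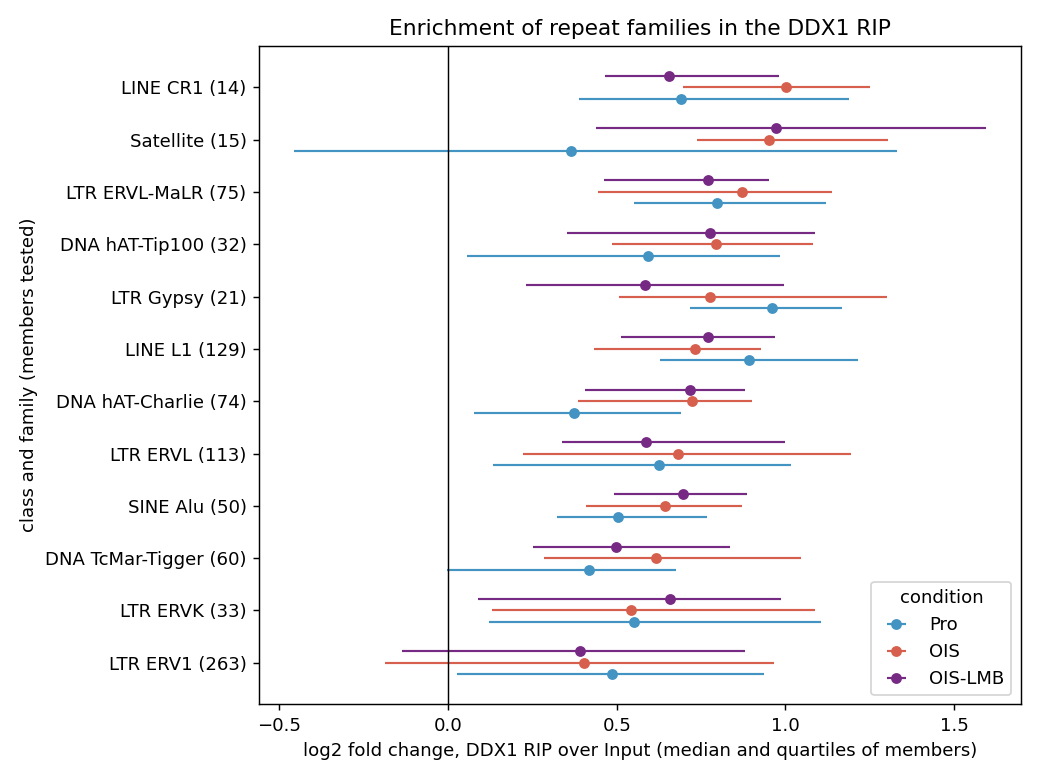
Median (points) and quartiles (lines) of the log2 fold change of DDX1 RIP over Input (x axis) for the tested members of 11 repeat families and all satellites (y axis, number of members in parentheses), by condition. The medians of all 12 sets lie above 0 in each condition, L1 at 0.89, 0.73 and 0.77 in Pro, OIS and OIS-LMB, and ERV1 at 0.48, 0.40 and 0.39.

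The same genes were largely recovered in the 3 conditions, which share no library. However, the calls came from a common fit with dispersions shared over all libraries, and OIS and OIS-LMB libraries of the same number deviated together. The numbers for independent lists are therefore only a loose reference. Among 19410 genes, 2711 were higher in RIP in all 3, where independent lists would share 126, and 3397 were lower in all 3, against 222. With separate fits on the groups compared, 1567 genes were higher in all 3. Of the genes higher in Pro, 82.9% were also called higher in OIS and 77.4% in OIS-LMB. Among repeats, 102 subfamilies were higher in all 3 conditions (7.82 for independent lists), and 3 were lower. These 3 were 7SK, MER11B and LTR48B. Across genes, which are not independent replicates, log2 enrichments correlated at 0.84 between Pro and OIS, 0.82 between Pro and OIS-LMB and 0.90 between OIS and OIS-LMB. Across repeats the correlations were lower, at 0.58, 0.52 and 0.77.

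The largest mean enrichments among genes called in all 3 conditions belonged to ENSG00000261512.2 (log2 5.29, 3.48 and 1.98 in Pro, OIS and OIS-LMB) and ENSG00000160223.17 (5.17, 3.16 and 2.31). The latter was not called in OIS without OIS Input replicate 2 (2.68), nor in OIS-LMB without any of its 4 libraries (2.03 to 2.55) or with library-size scaling alone (adjusted p = 0.0682). The largest mean depletions belonged to ENSG00000202354.1 (-7.56, -7.35 and -5.46) and ENSG00000201098.1 (-6.98, -6.71 and -6.10).

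Whether enrichment differed between OIS and control cells was tested directly. Senescence itself was not checked in these libraries. By adjusted p in the paired fit, though not by size, the clearest difference among repeats was alpha satellite ALR/Alpha, a main component of human centromeres. It was at 9.78 ± 1.60 CPM in Pro Input and 6.15 ± 1.01 in Pro RIP, but at 14.5 ± 0.76 in OIS Input and 32.4 ± 1.43 in OIS RIP (SD, n = 2). Its enrichment was 3.53-fold larger in OIS by the paired fit (log2 difference 1.82 ± 0.25, edgeR adjusted p = 0.00518). The unpaired fit, which was the one planned for this difference, gave a log2 difference of 1.82 ± 0.32 with an adjusted p = 0.85.

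LTR1A2 (log2 difference 1.46 ± 0.27) and MER46C (1.19 ± 0.21) were also more enriched in OIS than in Pro in the paired fit. LTR78 (-1.37 ± 0.27), LOR1-int (-1.35 ± 0.27) and L1PA14 (-1.30 ± 0.27) were less enriched. These 6 and LTR22B1, below the level limit, were the 7 subfamilies among 103 features called by the paired fit, with 42 genes higher and 54 lower. The unpaired edgeR fit called 0 features, with 548 at an unadjusted p under 0.05, and DESeq2 called 9. The count of 103 was 14 without Pro replicate 1, 11 without Pro replicate 2, 43 without OIS replicate 2, and 182 and 168 without OIS-LMB replicates 1 and 2. Higher features were 43.7% of the 103, 25.5% of the 51 called with library-size scaling alone, 72.7% without Pro replicate 2 and 51.2% without OIS replicate 2. ALR/Alpha lost its call without Pro replicate 2 (1.49, adjusted p = 0.1), and the other 5 named subfamilies lost theirs without either Pro replicate or without OIS replicate 2. These 5 were also not called by the paired fit with library-size scaling alone (adjusted p of 0.051 to 0.0757), and LOR1-int not without OIS replicate 1 (adjusted p = 0.12).

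By family, enrichment in OIS exceeded that in Pro for hAT-Charlie DNA transposons, with a median log2 difference of 0.35 over 74 members (camera adjusted p = 0.000147). The TcMar-Tigger transposons followed at 0.27 over 60 members (adjusted p = 0.00322), and L1 lay lower at -0.16 over 129 members (adjusted p = 0.043). With an estimated correlation these became adjusted p = 0.999 each. Library-size scaling lowered the median difference of all features by 0.14 and kept the 3 directions.

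Adding LMB to Ras cells left ALR/Alpha at 15.4 ± 0.32 CPM in Input and 30.3 ± 2.57 in RIP (SD, n = 2). For the difference between OIS-LMB and OIS enrichment, edgeR called 0 features, with 149 at an unadjusted p under 0.05. The paired fit also called 0, with 815 at an unadjusted p under 0.05, and DESeq2 called 1. Without OIS replicate 1 the paired fit called 5 features, and without OIS-LMB replicate 2 it called 2. None of the 13 repeat sets passed (lowest camera adjusted p = 0.0799, for Gypsy elements).

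**Figure D3:**
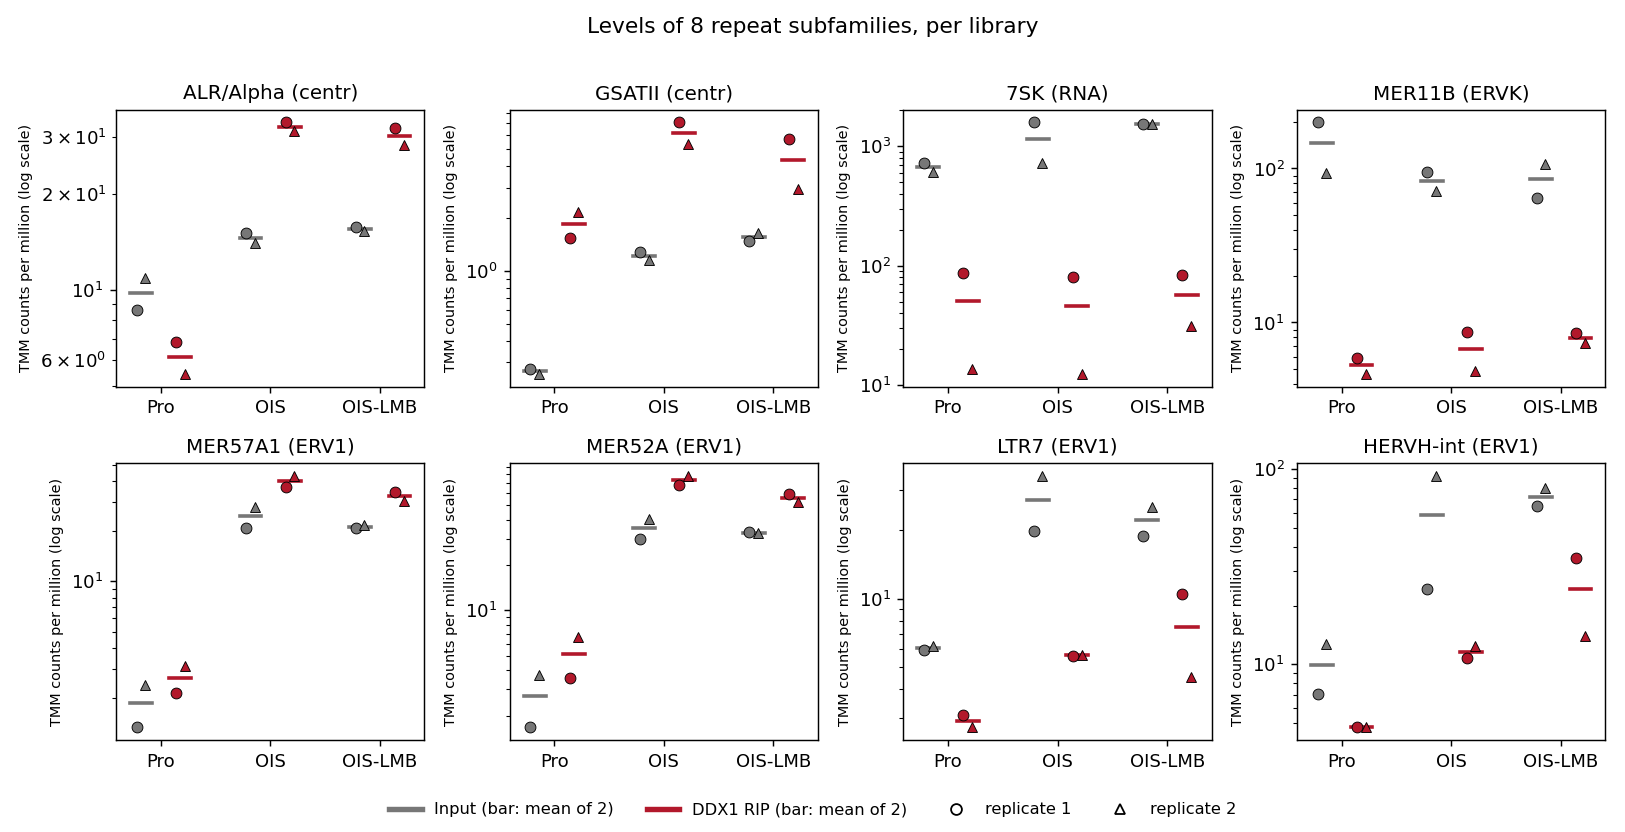
TMM CPM (log-scaled y axes) of 8 repeat subfamilies in Pro, OIS and OIS-LMB, with Input in grey, DDX1 RIP in red, circles for replicate 1, triangles for replicate 2 and bars for means of 2 libraries. ALR/Alpha RIP libraries lie below Input in Pro and above it in OIS and OIS-LMB, 7SK and MER11B RIP libraries lie below Input in each condition, and MER57A1 and MER52A are higher with ectopic Ras in Input and RIP.

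Input libraries carry the RNA levels of the cells. With ectopic Ras, MER57A1, an LTR of an ERV1 retrovirus, was 13.1-fold higher in OIS than in Pro Input (log2 3.71 ± 0.35, edgeR adjusted p = 0.000322), at 24.6 ± 5.02 against 1.87 ± 0.76 CPM (SD, n = 2). MER52A rose by log2 3.69 ± 0.43, from 2.72 ± 1.47 to 35.0 ± 7.21 CPM, and MER41B by 2.87 ± 0.59. HERVH-int (2.56 ± 0.62) and LTR7 (2.17 ± 0.41) rose together, as did GSATII (2.19 ± 0.42).

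UCON78 (3.79), L1M3c (2.42), LTR1D1 (2.37) and MER74B (2.24) were the other named increases in OIS Input. LTR103_Mam (-2.53), HERVL18-int (-2.27), MER57F (-2.19), MER51C (-1.39), LTR10C (-1.19) and LTR5A (-0.69), an LTR of HERV-K, fell. Of 263 ERV1 subfamilies 17 rose and 6 fell (camera adjusted p = 0.0594, 0.921 with an estimated correlation). Of 75 ERVL-MaLR 7 rose and 0 fell (camera adjusted p = 0.0443). The ERVL-MaLR set did not pass with library-size scaling (camera adjusted p = 0.0541), the replicate block over all libraries (0.124) or an estimated correlation (0.921). In all 1340 genes and 42 subfamilies rose and 1648 genes and 11 subfamilies fell, but the split of genes depended on the fit, with 2171 up and 2023 down by DESeq2 and 2256 up and 2302 down without a low-count filter. Adjusted over the repeats alone, 8 subfamilies rose and 0 fell.

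The count of 3041 features between OIS and Pro Input was 1208 without Pro Input replicate 1, 1051 without OIS Input replicate 1, 1932 without Pro Input replicate 2 and 1626 without OIS Input replicate 2. MER57A1 and MER52A were called with every library left out in turn, whereas each of the other named subfamilies lost its call without at least 1 of the 4 Pro and OIS Input libraries. HERVH-int was not called without OIS Input replicate 2 (log2 1.30), where it stood at 92.4 CPM against 24.4 CPM in replicate 1, nor without Pro Input replicate 1 (2.19) or Pro Input replicate 2 (3.04). A fit on the Pro and OIS Input libraries alone ended the calls of MER57F, LTR1D1, HERVH-int, MER51C, LTR10C and LTR5A (adjusted p of 0.0506 to 0.131). LTR5A was also not called under relative log expression factors (adjusted p = 0.0644), with library-size scaling alone (adjusted p = 0.0589) or without a low-count filter (adjusted p = 0.249), nor LTR10C without that filter (adjusted p = 0.111). Without Pro Input replicate 1 the calls of MER41B (2.76), LTR7 (2.14) and GSATII (2.24) were also lost. The 53 subfamilies became 6 without Pro Input replicate 1, 14 without OIS Input replicate 1, 26 without Pro Input replicate 2 and 20 without OIS Input replicate 2.

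Between OIS-LMB and OIS Input, edgeR called 68 features, with 3171 at an unadjusted p under 0.05, and the fit with the replicate block over all libraries called 1127, with 13 subfamilies. Among repeats, the ERV1 internal sequence HERVIP10B3-int rose from 1.66 ± 0.04 CPM in OIS to 8.29 ± 4.06 CPM in OIS-LMB Input (SD, n = 2; log2 2.32 ± 0.38, edgeR adjusted p = 0.0495). Besides it, 51 genes rose and 16 fell, against 605 and 509 with the replicate block and 457 and 484 by DESeq2. The median over 978 repeats was higher by log2 0.26 (camera adjusted p = 0.00227, 0.827 with an estimated correlation), with Gypsy at 0.65 and ERV1 at 0.32 (adjusted p = 0.00272 and 0.00176, both 0.827 with an estimated correlation). DESeq2 called 956 features. A fit on the OIS and OIS-LMB Input libraries alone did not call HERVIP10B3-int (edgeR adjusted p = 0.266) or any other feature. Leaving out any of the 4 OIS and OIS-LMB Input libraries ended all 68 edgeR calls, leaving out any of the other 8 libraries left 10 to 42, and HERVIP10B3-int lost its call without each of the 12 libraries.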

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

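The comparison of OIS-LMB with Pro enrichment, the repeat family sets and both tests of the alpha satellite pattern were chosen after the values had been seen. The paired fit of enrichment differences was also outside the fixed plan. Each result here met a test of the difference between the enrichments of 2 conditions, single subfamilies in the paired fit and families in the unpaired one. Between OIS and Pro, log2 enrichment differed for ALR/Alpha (1.82), LTR1A2 (1.46), MER46C (1.19), L1PA14 (-1.30), LOR1-int (-1.35), LTR78 (-1.37) and LTR22B1 (-3.14). The unpaired edgeR fit called 0 features there (548 at an unadjusted p under 0.05, DESeq2 9).

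Between OIS-LMB and Pro the paired fit called 519 features, with 195 genes higher and 311 lower, while the unpaired edgeR fit called 0 (836 at an unadjusted p under 0.05, DESeq2 30), the replicate block over all libraries 4 and edgeR without a low-count filter 36. The 519 became 36 and 39 without Pro replicates 1 and 2, and 265 and 153 without OIS-LMB replicates 1 and 2. Enrichment was larger in OIS-LMB for MER106B (2.35), LTR47B2 (1.91), CER (1.81), MER5C1 (1.76), ALR/Alpha (1.64), MER46C (1.00), MER5A1 (0.99) and L4_A_Mam (0.88). It was smaller for L1PA14 (-1.09), MLT1L (-1.14), HERVK22-int (-1.71), LTR1D1 (-1.80) and LTR22B1 (-3.53). The 9 of these above the level limit each lost the call without at least 1 culture, among them, without Pro replicate 2, CER (1.19, adjusted p = 0.469), ALR/Alpha (1.30, adjusted p = 0.0787) and LTR1D1 (-2.57, adjusted p = 0.0787). LTR1D1, L1PA14, MER46C, MER5A1 and L4_A_Mam were also not called by the paired fit with library-size scaling alone (adjusted p of 0.0534 to 0.12). The calls of MER106B, LTR47B2, MER5C1 and LTR22B1 were not followed without each culture. Both comparisons use the same Pro libraries, so the subfamilies found in both are not independent evidence. Family medians differed between OIS and Pro for hAT-Charlie (0.35), TcMar-Tigger (0.27) and L1 (-0.16), and between OIS-LMB and Pro for hAT-Charlie (0.28, camera adjusted p = 0.0201). With an estimated correlation the adjusted p were 0.999 for the first 3 and 0.986 for the last.

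Alpha satellite averaged 6.15 CPM in RIP and 9.78 CPM in Input in Pro, where its call was lost without 8 of the 12 libraries, and 32.4 and 14.5 CPM in OIS. The other 977 subfamilies had a median paired difference of 0.0594, so repeats as a whole did not rise by the size seen for ALR/Alpha. In the unpaired fit the median of all repeats was 0.0588, and -0.0683 with library-size scaling. ALR/Alpha ranked 11, with a lower end of 1.31, but it was picked for its difference. That its lower end lay above the median of the others was therefore bound to follow and is no test of a general rise. The lowest difference without 1 of the 4 cultures was 1.49 (without Pro replicate 2), and the call was lost there. ALR/Alpha was singled out by its adjusted p in the paired fit, which favours subfamilies whose cultures agree. That the difference kept much of its size therefore cannot decide on a single culture as the source. Whether ectopic Ras changes recovery of centromeric RNA with DDX1 stays open as a hypothesis, as do reads from 1 locus or from a host transcript. The unpaired adjusted p of 0.85 and 2 cultures per condition leave it a pattern to test again.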

How the results depend on the processing

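The adjustment over repeats alone, the tests of repeat shares and all alternatives within the paired fit were chosen after the values had been seen. No named feature turned its direction, but medians near 0 and splits of calls did. The median OIS minus Pro difference over repeats went from 0.0588 to -0.0683 with library-size scaling, where those of hAT-Tip100, ERVL, ERVL-MaLR, Gypsy and Alu also turned negative. Genes between OIS and Pro Input went from 1340 higher and 1648 lower to 2171 and 2023 with DESeq2, genes between OIS-LMB and OIS Input from 51 and 16 to 457 and 484, and paired OIS minus Pro genes from 42 and 54 to 8 and 3 without Pro replicate 2. The cause of the moves below was not tested, except that leaving out libraries or pooling fewer groups lowers the degrees of freedom. The replicate block within condition moved the calls of RIP against Input to 12855 in Pro, 13150 in OIS and 12793 in OIS-LMB, with 487, 535 and 506 subfamilies, and the OIS minus Pro difference from 0 to 103, with 7 subfamilies. The replicate block over all libraries gave 307, 355 and 321 subfamilies, 2 OIS minus Pro differences, 5582 changes between OIS and Pro Input with 107 subfamilies, and 1127 between OIS-LMB and OIS Input with 13. DESeq2 called 9 OIS minus Pro differences with 1 subfamily, 1 OIS-LMB minus OIS difference, 956 features between OIS-LMB and OIS Input with 15 subfamilies, and 96 subfamilies between OIS and Pro Input. Without a low-count filter edgeR called 9 and 6 differences, 897 features with 12 subfamilies between OIS-LMB and OIS Input, and 4642 with 84 between OIS and Pro Input, and a filter of 5 CPM gave 135 between OIS-LMB and OIS Input. Library-size scaling gave 110, 114 and 89 subfamilies in Pro, OIS and OIS-LMB, and 51 paired differences. Adjusted over repeats alone, 72, 135 and 96 subfamilies were called, 8 between OIS and Pro Input and 0 between OIS-LMB and OIS Input. Fits on the groups compared called 4519 features in OIS-LMB with 39 subfamilies, 33 subfamilies between OIS and Pro Input, and 0 features and 0 subfamilies between OIS-LMB and OIS Input, and 1567 genes were then higher in all 3 conditions. Leaving out each library gave 5391 to 8452 features in Pro (57 to 221 subfamilies), 5825 to 8785 in OIS (81 to 262), 5782 to 7740 in OIS-LMB (54 to 241), 0 to 0 for both unpaired differences, 1051 to 3242 between OIS and Pro Input (6 to 61), 0 to 42 between OIS-LMB and OIS Input (0 to 0) and 1958 to 2529 shared genes. Leaving out each culture gave 11 to 182 paired OIS minus Pro and 0 to 5 paired OIS-LMB minus OIS differences. The repeat share difference ran from 0.266 to 0.628 points, with an exact permutation p above 0.05 for 9 of 12 libraries, among them 0.441 points (p = 0.0648) without Pro Input replicate 1. The named subfamilies and the gene IDs given above made up 93 results. Of these, 46 kept their call without each library, or culture in the paired fit. The other 47 lost it at least once, all 15 paired ones among them. Among the gene IDs, only ENSG00000160223.17 lost calls, in OIS and OIS-LMB, so the named subfamilies alone were less stable than these numbers. Scaling without mitochondrial, ribosomal and small structured RNA genes, the gene lists and the label check were not run, because no gene ID could be paired with a symbol.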

Other observations

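The tests of the broad repeat enrichment were chosen after the values had been seen, whereas the test of 7SK carry-over was not. Satellite rows together held 19.0 ± 4.68 CPM in Pro Input, 30.8 ± 2.53 in OIS Input and 41.9 ± 2.76 in OIS-LMB Input (SD, n = 2). In RIP they held 20.6 ± 1.70, 54.5 ± 0.491 and 74.1 ± 0.623 CPM, and the sums were not tested between conditions.

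Repeat subfamilies were broadly higher in RIP than in Input. Scaling factors are argued against as the whole source, since under total-count scaling the median log2 ratio over repeats was above 0 in 6 of 6 pairs of RIP and Input, averaging 0.371 ± 0.0468 (SE between the pairs). Genomic DNA in RIP would add gene rows seen in RIP alone. At equal depth their number was at most 0.765 of those seen in Input alone, with 643 against 841 rows in Pro. Fewer gene rows had a count in RIP than in Input (23421 and 24299, exact permutation p = 0.0185, adjusted p = 0.0265). RNAs lost in the pull-down leave rows seen in Input alone with or without DNA, so these counts cannot decide on genomic DNA. Unspliced RNA with repeats in its introns was not tested. Both stay open beside binding of repeat RNA itself.

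7SK counts were higher in RIP replicate 1 than in RIP replicate 2, by 7.21-fold in Pro, 6.67-fold in OIS and 2.85-fold in OIS-LMB, against 1.16-fold, 1.95-fold and 1.02-fold in Input. Unbound Input RNA left in replicate 1 would set a floor under all RNAs, so that few genes could lie under 0.5 of the 7SK ratio. The share of genes that did was 1.39% in Pro, 0.222% in OIS and 0.115% in OIS-LMB, on both sides of the limit of 1% set beforehand, so carry-over cannot be told apart from a true difference between replicates. In replicate 2, set against its own 7SK ratio, the share was 0.133%, 0.0987% and 0.00822%. A low share was thus also seen where 7SK was lower in RIP, so it says little about carry-over. No biological explanation was tested.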
